A study of Drosophila melanogaster with 15 samples.

How the data were processed

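RNA levels were measured in Drosophila melanogaster embryos at 5 stages with 3 arrays each, 15 arrays in all. Per the labels' protocols, eggs were collected in short windows, embryos were aged at room temperature and selected by hand under oil for their morphology, and total RNA was extracted with Trizol and made into biotin-labelled cRNA for Affymetrix Drosophila arrays. The labels name yellow white and Oregon R for all stages, as the parents for T0 and T1 and as the embryos for T2 to T4. No batch is named in the labels. Group and replicate number were taken from the sample titles, and all 15 columns of the table matched 1 sample each.

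The deposited values are linear signals, 1 per probe set and array, and MAS5 is named for them per the submitters' processing notes, with its version not given in the sources used here. In the deposited signal values the 2% trimmed mean of every array was 100, so that a change is relative to the average signal of its array. No detection call was used. The table held 14010 probe sets. The 44 control probe sets were left out of the tests, and 13966 were tested. Of these 12443 had 1 gene symbol, 327 several and 1196 none in the platform annotation, and symbols were updated or kept through Entrez identifiers for 12394. No gene was named from a probe set with several symbols. Where a gene had several probe sets, the one with the highest mean over the 15 arrays stood for it. Of 1209 such genes 4 had probe sets called in opposite directions for T1 against T0, 2 for T2 against T1, 0 for both later steps and 12 for T4 against T0.

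As a background level the 95th percentile of the signals of 23 negative-control probe sets was taken, 21.96. Between 39.0% and 49.7% of the signals of an array lay below it, and the median signal of an array was between 22.2 and 36.2. The number of arrays limits the precision.

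Signals were tested as log2(signal + 7.3), where 7.3 is the median over arrays of the 25th percentile of signals, so that fold changes are on this scale and understate the change of dim genes. One linear model with a mean per stage was fitted to all arrays with limma 3.58.1 (with statmod 1.5.0) in R 4.3.3, and moderated statistics were computed with eBayes, with a median of 13.6 degrees of freedom. Contrasts were T1 against T0, T2 against T1, T3 against T2, T4 against T3 and T4 against T0. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 per contrast and a log2 fold change of at least 1 in size. A moderated F test over the 4 successive contrasts, at an adjusted p under 0.05, gave the probe sets that changed at any stage. The cellularisation class needed the mean of T1 and T2 to exceed T0, and the mean of T3 and T4, by at least 1 on the log2 scale with adjusted p under 0.05 in both tests.

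The comparisons, the thresholds, the alternatives, the rule for named genes and 23 gene lists were fixed before the data were examined. The lists were zygotic cellularisation, gap and head gap, pair-rule, segment polarity, Hox, dorsal ectoderm and amnioserosa, mesoderm and gastrulation, neurogenic ectoderm, proneural and Notch pathway, sex chromosome counting, maternal egg activation and localised transcripts, pole cell and germ plasm, cell cycle, maternally supplied cellularisation and polarity machinery, hemocyte, tracheal and salivary gland, late differentiation, eggshell and yolk protein, heat shock, cell death, glycolysis, cytoplasmic ribosomal, mitochondrial ribosomal and proteasome genes. Members without a probe set of their own were not analysed here, and list counts are out of the measured members. Measured were, for example, 3 of 9 listed neurogenic ectoderm genes, 4 of 8 Hox, 5 of 13 heat shock and 36 of 92 cytoplasmic ribosomal genes. List shifts were tested with camera of limma at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. Named genes were the 5 highest and 5 lowest called log2 fold changes without overlap of the stages, in each list up to 4 called members per direction and 2 uncalled ones with the highest signal, and the 10 leading members of the class. Among the highest and lowest, genes known only by a CG number could be passed over for the next gene.

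Alternatives were quantile normalization, centring on the array median or on cytoplasmic ribosomal proteins, pseudocounts of 1 and of 29.6 (the median signal), leaving out the dimmest 40% of probe sets, an intensity trend with robust settings, array weights, the replicate number as a block, the 2 stages alone and each array left out in turn. Centring on the 9 hybridisation-control probe sets and the group of transcripts low at T1 were chosen after seeing the data. The pipeline was tested on simulated data over 13966 probe sets. For T1 against T0 84% of 50 probe sets changed by 1.5 on the log2 scale were called. Of those changed by 2 it called 92% and of those changed by 3 100%, with 13 unchanged probe sets called. Changes were put only into probe sets of intermediate mean log2 signal, so recovery among the dimmest and the brightest was not tested.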

Results

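Transcript levels were measured on Affymetrix expression arrays in whole Drosophila melanogaster embryos, which had been picked by hand for their morphology at 5 stages. Stage T0 held embryos younger than nuclear cycle 9, before zygotic transcription, when the RNA of the egg comes from the mother. Stages T1 and T2 held embryos in the slow and the fast phase of cellularisation, when membranes close around the nuclei of the syncytial blastoderm. The sample labels place T3 and T4 at the start and the end of germ band elongation, whereas the series text places them at the start and the end of gastrulation. The sample labels were followed, and which of both describes the embryos stays open. Each stage had 3 arrays, 15 in all, and their number limits the precision. Signals are array units scaled to a mean of 100 per array, and values below are the mean signal ± SD of the 3 arrays (n = 3). A probe set was called where its adjusted p in limma was under 0.05 and its log2 fold change was at least 1 in size. The p-values measure only the spread between these samples, which may be technical, because the labels do not say that replicates came from separate collections. Arrays of 1 stage correlated with Pearson r between 0.925 and 0.964 over all probe sets, and arrays of different stages with r between 0.749 and 0.949.

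**Figure D1:**
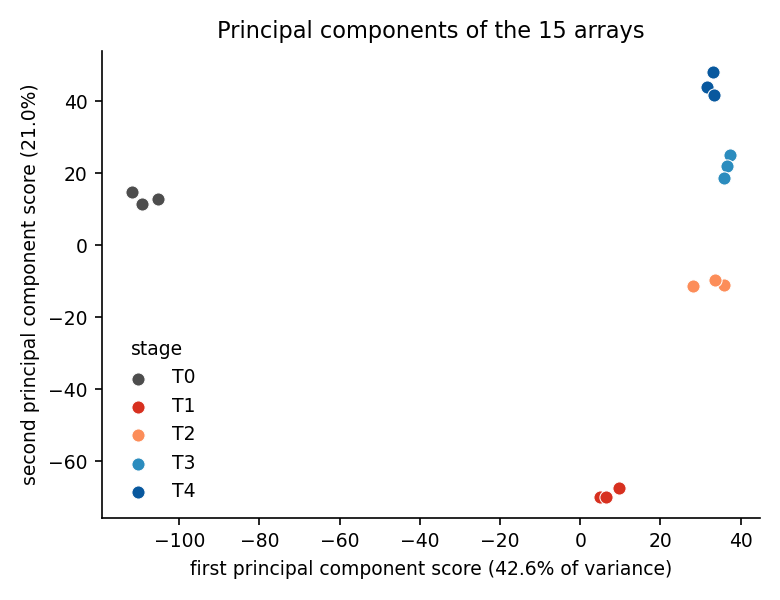
Each point is 1 array, placed by its scores on the first and second principal components (arbitrary units) of the log2 signals, which hold 42.6% and 21% of the variance, and coloured by stage. The 3 arrays of each stage lie together, and T0 lies apart from the later stages on the first component.

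The comparison of T1 with T0 asked which transcripts appear and which are lost between the maternal period and the onset of cellularisation. Z600, an inhibitor of mitosis in the blastoderm, rose from 2.90 ± 0.557 to 6752 ± 535, at least 307-fold, and halo, a gene for the transport of lipid droplets during cellularisation, rose from 14.8 ± 4.02 to 4672 ± 480, at least 212-fold. The gene term rose at least 317-fold to 6983 ± 824, SNCF at least 140-fold to 3086 ± 249, and bard at least 99.3-fold to 2190 ± 244. Maternal transcripts fell in the same interval. BicC, an RNA-binding protein of oogenesis, went from 1345 ± 146 to 4.70 ± 1.40, at least 61.0-fold lower. In the same step exu, which helps to localise bicoid RNA, went from 3075 ± 684 to 35.9 ± 25.3, with a log2 fold change of -6.37 ± 0.60 (SE). The small heat shock protein gene Hsp26 (6763 ± 1680 to 72.9 ± 9.23), fs(1)Ya, a nuclear envelope protein of the earliest mitoses (2040 ± 387 to 25.7 ± 8.74), and yin (2787 ± 211 to 18.9 ± 11.6) also fell. In a fold given as "at least", the dim side stands at 21.96, the 95th percentile of the signals of the negative-control probe sets, because its 3 arrays all lay at or below that level, and the bright side is the mean of the log2 signals.

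The zygotic cellularisation, gap, pair-rule, dorsal ectoderm and proneural lists rose. All 7 measured zygotic cellularisation genes were called higher, and 7 when adjusted over the list alone (camera adjusted p = 5.8e-10). Besides Z600 and halo they were slam, needed for membrane growth (486 ± 49.5 to 8764 ± 872), Sry-alpha (42.1 ± 6.75 to 5056 ± 291) and nullo (11.8 ± 7.49 to 422 ± 67.1), which act on actin at the cleavage furrow. The others were kuk, a nuclear lamina protein (953 ± 94.7 to 4020 ± 355), and bnk, a regulator of the actin network (3.13 ± 2.23 to 30.7 ± 15.1, at least 1.28-fold). The bnk call ended with arrays centred on ribosomal proteins (adjusted p in limma 0.068) and with a pseudocount at the median signal (log2 fold change 0.85). Of 12 gap and head gap genes, 10 were called higher and 10 when adjusted over the list alone (camera adjusted p = 5.8e-10). Among them were gt, which reached 604 ± 32.8, Kr with 521 ± 90.7 and tll with 411 ± 13.8. The gap gene hb, which is also supplied by the mother, had 567 ± 45.9 at T0 and 970 ± 114 at T1 and was not called. All 7 measured pair-rule genes were higher, 7 when adjusted over the list alone (camera adjusted p = 5.4e-08), with opa, hry and ftz reaching 386 ± 115, 609 ± 186 and 1004 ± 133. Of 13 dorsal ectoderm and amnioserosa genes 9 were higher, 9 when adjusted over the list alone (camera adjusted p = 7e-06). They were led by tld, a protease that releases Dpp (795 ± 97.5 at T1), and the homeobox gene zen (698 ± 97.1). Of 21 proneural and Notch pathway genes 15 were higher, 15 when adjusted over the list alone (camera adjusted p = 5.8e-10). They included the Notch signalling inhibitor Tom (24.0 ± 29.5 to 1439 ± 246) and mira, an adaptor of asymmetric neuroblast division (18.2 ± 11.9 to 1397 ± 233).

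Some patterning lists were split at T1. The mesoderm genes twi (to 1139 ± 119) and sna (to 1385 ± 49.4) rose, whereas T48, needed for mesoderm invagination, went from 122 ± 13.7 to 6.30 ± 2.26 and zfh1 from 185 ± 18.3 to 22.2 ± 9.50. Of the 9 measured mesoderm and gastrulation genes 4 were higher and 2 lower, 4 and 2 when adjusted over the list alone, and the list did not pass the test (camera adjusted p = 0.27). Of 9 segment polarity genes 2 were higher and 1 lower, and 2 and 1 when adjusted over the list alone (camera adjusted p = 0.14). Of 4 Hox genes 1 was higher, 1 when adjusted over the list alone (camera adjusted p = 0.28). The Hox call, for Dfd, lay between 6.53 ± 5.19 and 19.7 ± 1.91, both below the negative-control level, so that it has no fold. It ended without T0 replicate 2 or 3 or T1 replicate 1, where the fitted log2 difference was 0.85 to 0.97. Of 3 neurogenic ectoderm genes 2, the FGF ligand genes ths and pyr, were higher, 2 when adjusted over the list alone (camera adjusted p = 0.27). The T0 means of both lay below the negative-control level, and ths reached 22.4 ± 4.44, at least 1.01-fold, while pyr went from 13.7 ± 10.1 to 35.2 ± 10.4. Their calls each ended without T0 replicate 3 or 4 or T1 replicate 2 or 3, with fitted log2 differences from 0.90 to 1.12 for ths and from 0.82 to 1.06 for pyr, and with the replicate number as a block (adjusted p in limma 0.077 and 0.069). The calls for Dfd, ths and pyr also ended with arrays centred on ribosomal proteins (0.32, 0.41 and 0.39 on the log2 scale), centred on the hybridisation controls (0.52, 0.61 and 0.59) and with a pseudocount at the median signal (0.46, 0.52 and 0.60). With only the arrays of T0 and T1 in the fit the call for pyr ended (adjusted p in limma 0.056). Of 7 genes of the sex chromosome counting list 6 were higher and 1, da, was lower, 6 and 1 when adjusted over the list alone (camera adjusted p = 0.0014, and adjusted p = 0.053 with an estimated correlation). Of the 6 hemocyte, tracheal and salivary gland genes 1 was higher and 1 lower, 1 and 1 when adjusted over the list alone (camera adjusted p = 0.39).

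The egg activation, pole cell and glycolysis lists fell. Of 16 egg activation and localised transcripts 12 were lower and none higher, 12 when adjusted over the list alone (camera adjusted p = 1.5e-07). They included osk, the organiser of the germ plasm (1734 ± 265 to 42.1 ± 2.26), and png, a kinase of egg activation (556 ± 15.2 at T0, below the negative-control level at T1). In contrast stau had 263 ± 25.8 and 419 ± 26.7 and was not called. Of 9 pole cell and germ plasm genes 7 were lower, 7 when adjusted over the list alone (camera adjusted p = 0.00037), among them vas (565 ± 57.9 to 12.2 ± 7.84). Of 8 glycolysis genes 6 were lower, 6 when adjusted over the list alone (camera adjusted p = 2.2e-06). Gapdh1 went from 2707 ± 185 to 332 ± 59.8, Pgk from 1055 ± 34.7 to 60.5 ± 5.62 and Pgi from 885 ± 145 to 55.1 ± 11.1, while Ald1 had 1236 ± 89.8 and 1537 ± 302 and was not called. Of 5 heat shock genes 3 were lower and 1 higher, 3 and 1 when adjusted over the list alone (camera adjusted p = 0.031, adjusted p = 0.071 with an estimated correlation and 0.057 with the replicate number as a block). Of 39 proteasome subunits 6 were lower and 2 higher, 6 and 2 when adjusted over the list alone, and the list did not pass the test (camera adjusted p = 0.83). Its median was 0.42 and its mean -0.13 on the log2 scale, the median being -0.28 centred on ribosomal proteins and -0.08 centred on the hybridisation controls. The lower members included Rpn11 (982 ± 205 to 61.0 ± 9.60) and Rpn8 (490 ± 78.9 to 50.4 ± 9.50). All 6 belonged to the regulatory particle. Its 14 subunits had a median of -0.97 on the log2 scale (-1.67 centred on ribosomal proteins), against 0.68 for the 12 of the core particle (-0.02 with that centring). Subunits whose symbols end in T or R, with or without a number, were left out of these 14 and 12. Neither particle held a higher call, so the 2 higher subunits were among those left out. This grouping was made after the values were seen, and the difference was not tested. Of 64 mitochondrial ribosomal proteins 14 were lower, 14 when adjusted over the list alone (camera adjusted p = 0.22), led by mRpL38 (469 ± 69.9 to 24.8 ± 16.7).

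Of 14 cell cycle genes 6 were lower and 1 higher, 6 and 1 when adjusted over the list alone (camera adjusted p = 0.26). The higher one was trbl, which promotes the degradation of Cdc25 phosphatase (200 ± 20.0 to 1816 ± 73.3), and the checkpoint kinases lok (773 ± 12.8 to 103 ± 10.6) and grp (1155 ± 48.2 to 318 ± 39.2) fell. Of 19 genes of the maternally supplied cellularisation and polarity machinery 8 were higher and 1 lower, 8 and 1 when adjusted over the list alone (camera adjusted p = 4.9e-05, and adjusted p = 0.067 with an estimated correlation). They included the junction genes shg, which encodes E-cadherin (93.4 ± 40.8 to 379 ± 44.6), and sdt, and the golgin gene lva went from 268 ± 46.3 to 82.9 ± 21.3. None of 36 cytoplasmic ribosomal proteins was called in limma, 0 also when adjusted over the list alone, although 27 had an unadjusted p under 0.05. Their median stood 0.62 higher on the log2 scale (camera adjusted p = 1.7e-06, adjusted p = 0.21 with an estimated correlation and also 0.21 after quantile normalization), but was 0.12 with arrays centred on the hybridisation controls. With arrays centred on the ribosomal proteins themselves it was -0.08, a value near 0 by construction. In limma none of the 10 late differentiation genes, 15 eggshell and yolk protein genes or 4 cell death genes was called, 0 also when adjusted over the list alone (camera adjusted p = 0.26, 0.82 and 0.26). An unadjusted p was under 0.05 for 2, 0 and 2 of them. Examples were Act87E (850 ± 119 and 1579 ± 201, called higher only with arrays centred on the median, at 1.06 on the log2 scale), Cp18 (79.0 ± 26.9 and 94.3 ± 16.1) and Dronc (199 ± 11.7 and 298 ± 17.2).

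In all, 1092 probe sets were called higher and 2097 lower at T1 than at T0, from 919 and 1826 genes, and 136 and 382 of them changed by at least 3 on the log2 scale. The share called higher was 34.2% as deposited. It was 44.8% (1439 higher and 1774 lower) after quantile normalization, 47.7% (1716 and 1880) with arrays centred on the median, 7.62% (299 and 3626) centred on ribosomal proteins and 10.7% (342 and 2844) centred on the hybridisation controls, a centring chosen after seeing the data. The median log2 fold change of all probe sets was 0.08 as deposited, -0.63 with the ribosomal centring and -0.43 with the hybridisation controls. Changes as deposited were not centred on this median.

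**Figure D2:**
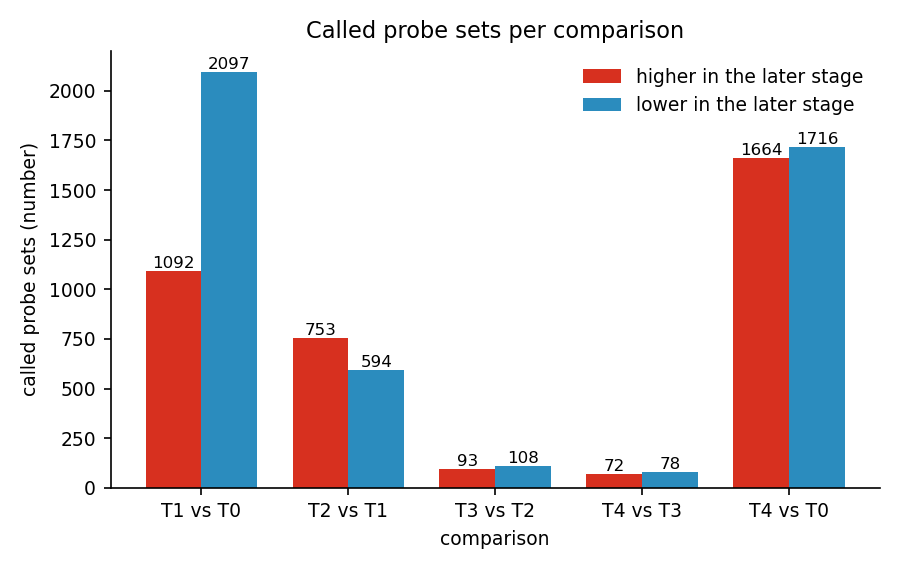
Bars give the number of probe sets called higher (red) and lower (blue) in the later stage of each comparison, out of 13966 tested, with the number above each bar. The counts were 1092 and 2097 from T0 to T1, 93 and 108 from T2 to T3 and 72 and 78 from T3 to T4.

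The comparison of T2 with T1 covered the passage from the slow to the fast phase of cellularisation. The homeobox gene ind, which specifies intermediate neuroblasts, rose from 7.00 ± 1.65 to 245 ± 3.79, at least 11.2-fold, and the segment polarity gene gsb from 6.23 ± 2.06 to 178 ± 44.5, at least 7.95-fold. T48 returned to 146 ± 14.3, and Prim2, a primase subunit for DNA replication, rose from 7.10 ± 0.557 to 167 ± 24.2, at least 7.55-fold. Cellularisation genes fell, with slam at 436 ± 95.9, a log2 fold change of -4.32 ± 0.24 (SE), and nullo at 12.6 ± 0.643, at least 19.1-fold lower. So did mol (571 ± 29.6 to 20.6 ± 12.4), the nuclear receptor gene ftz-f1 (178 ± 33.9 to 3.10 ± 1.83) and Elba3, a subunit of an insulator complex of the early embryo (1460 ± 259 to 78.5 ± 17.1).

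Of the 7 zygotic cellularisation genes 5 were lower, 6 when adjusted over the list alone (camera adjusted p = 5.3e-10), while kuk stayed at 4127 ± 151 and was not called. Of 12 gap and head gap genes 3 were lower, 3 when adjusted over the list alone (camera adjusted p = 0.00014), namely tll (74.6 ± 11.6 at T2), hb (283 ± 54.1) and kni (166 ± 22.2). Of 9 segment polarity genes 5 were higher, 5 when adjusted over the list alone (camera adjusted p = 1.4e-05), including en, the marker of posterior compartments (13.5 ± 9.03 to 75.4 ± 35.3), and nkd (94.3 ± 20.4 to 316 ± 73.7). All 3 measured neurogenic ectoderm genes, of 9 listed, were higher, 3 when adjusted over the list alone (camera adjusted p = 0.00014). The call for ths, which had a log2 fold change of 1.26, ended without T1 replicate 1, 2 or 3 or T2 replicate 3, where the value lay between 0.90 and 1.36. Of 21 proneural and Notch pathway genes 9 were higher, 10 when adjusted over the list alone (camera adjusted p = 8.1e-05). They included Brd (284 ± 16.5 to 1260 ± 52.9) and the Notch targets E(spl)malpha-BFM (22.9 ± 13.1 to 207 ± 38.3) and E(spl)m5-HLH (26.8 ± 9.12 to 207 ± 11.9). Of 9 mesoderm and gastrulation genes 4 were higher, 4 when adjusted over the list alone (camera adjusted p = 0.0061, and adjusted p = 0.11 with an estimated correlation), with zfh1 at 171 ± 20.8. The median of that list was 0.11 on the log2 scale, but -0.14 with arrays centred on the median and -0.01 centred on ribosomal proteins. Of 13 dorsal ectoderm and amnioserosa genes 7 were higher and 1 lower, 7 and 2 when adjusted over the list alone (camera adjusted p = 0.093, but 0.032 after quantile normalization and 0.023 centred on the median). Examples were the GATA factor pnr rising from 4.87 ± 2.92 to 51.5 ± 4.56 and zen falling to 260 ± 46.4. Of 6 hemocyte, tracheal and salivary gland genes 2 were higher, 2 when adjusted over the list alone (camera adjusted p = 0.04, and adjusted p = 0.099 with an estimated correlation), led by gcm (18.6 ± 13.4 to 86.7 ± 16.4). The call for sage (1.05 on the log2 scale) ended without T1 replicate 1 or 2 or T2 replicate 4, with values from 0.86 to 1.04. With the replicate number as a block the calls for ths and sage ended (adjusted p in limma 0.079 and 0.061). Both also ended after quantile normalization (0.079 and 0.060) and centred on the median (0.10 for both) or on ribosomal proteins (0.072 and 0.052), and in a fit of the 6 arrays alone (0.071 and 0.058). With a pseudocount at the median signal their log2 fold changes were 0.86 and 0.72, and with a pseudocount of 1 the call for ths ended (adjusted p in limma 0.058). Of 16 maternal egg activation and localised transcripts 7 were lower, 7 when adjusted over the list alone (camera adjusted p = 8.7e-08). They included smg, a repressor of maternal RNA (760 ± 46.8 to 74.6 ± 28.1), and the Cdc25 phosphatase gene twe (215 ± 32.9 to 23.7 ± 16.5). The other 14 lists did not pass the test.

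In all, 753 probe sets were higher and 594 lower at T2 than at T1, from 654 and 523 genes. The median log2 fold change of all probe sets was 0.14, over 0.1, and changes as deposited were not centred on it. The share called higher was 55.9% as deposited, 32.1% (421 and 889) with arrays centred on the median, 44.2% (556 and 702) centred on ribosomal proteins and 71.0% (919 and 376) centred on the hybridisation controls. Of the 1347 calls, 398 were rises of probe sets called lower from T0 to T1 and 104 were falls of probe sets called higher. Such overlaps were 0 and 0 in simulated data without any change, an outcome all but fixed in advance that cannot show what shared arrays add. Independent lists would share 113 and 46.4. Part of the excess may come from the shared arrays, since 3 arrays cannot be split into parts that each keep several.

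**Figure D3:**
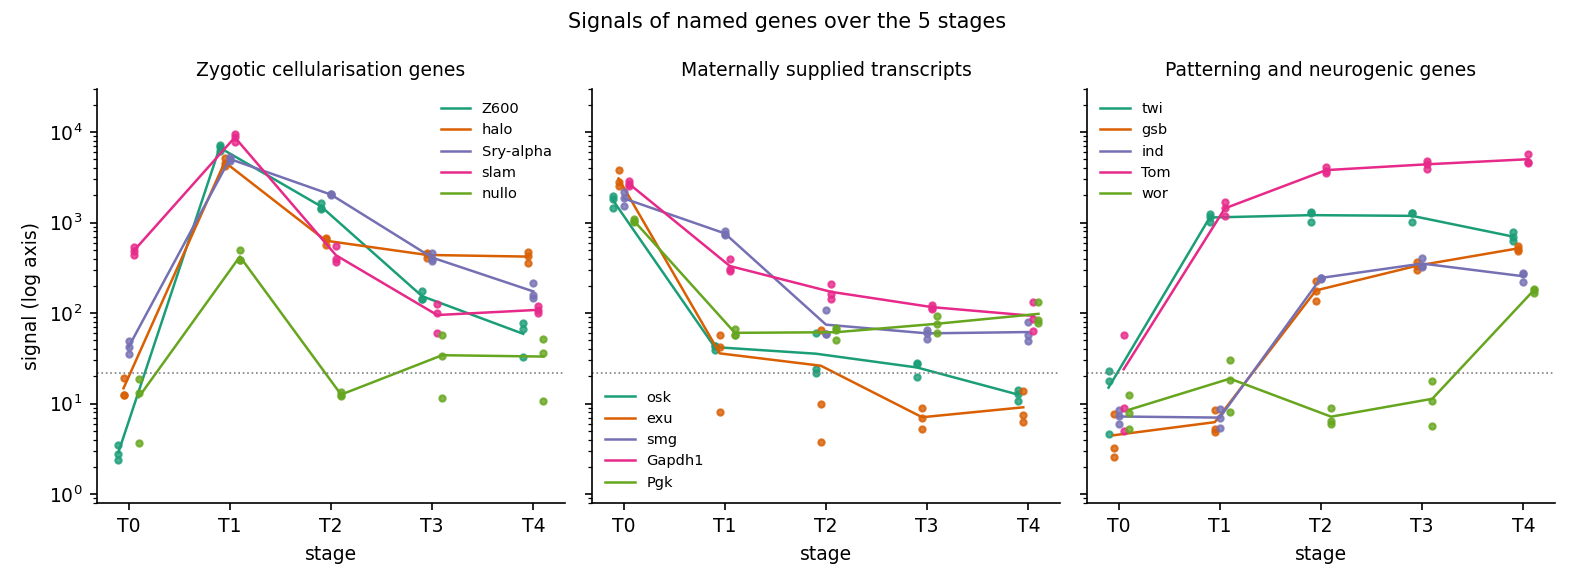
Signals on a log axis (array units) for 15 genes over the 5 stages, with points for single arrays, lines through the means of 3 arrays and a dotted line at the negative-control level of 21.96. Cellularisation genes such as slam peak at T1 (8764 ± 872), osk and Gapdh1 are highest at T0, and ind and gsb appear at T2 while wor appears at T4.

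The comparison of T3 with T2 followed embryos from cellularisation into the start of germ band elongation. Among the strongest falls, Z600 went from 1518 ± 127 to 154 ± 19.2, a log2 fold change of -3.24 ± 0.24 (SE). The insulator gene Elba2 went from 842 ± 88.6 to 92.7 ± 5.62 and Elba3 from 78.5 ± 17.1 to 8.33 ± 10.4, at least 3.52-fold lower. The cellularisation gene Sry-alpha went from 2042 ± 12.7 to 411 ± 47.8 and Mabi from 348 ± 3.94 to 67.4 ± 16.6. Among the strongest rises were those of Msh6, a DNA mismatch repair gene (51.8 ± 18.6 to 250 ± 23.1), bbg (44.2 ± 21.5 to 208 ± 27.1), the mesodermal factor zfh1 (171 ± 20.8 to 691 ± 53.6) and CadN, which encodes N-cadherin (49.5 ± 13.5 to 202 ± 20.9).

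Of the 7 zygotic cellularisation genes 3 were lower, 3 when adjusted over the list alone (camera adjusted p = 2e-06), slam being the other with 95.2 ± 32.7 at T3. Of 21 proneural and Notch pathway genes 3 were higher and 1 lower, 6 and 1 when adjusted over the list alone (camera adjusted p = 7.4e-06), with the Snail family gene esg rising from 197 ± 49.2 to 538 ± 65.3. The other higher calls, for ac and E(spl)mdelta-HLH, had T2 signals below the negative-control level. They rose from 6.50 ± 5.45 to 32.9 ± 8.02, at least 1.47-fold, and from 5.60 ± 6.79 to 37.2 ± 4.21, at least 1.69-fold, so that neither bound reaches the threshold of 2-fold. The call for ac (a fitted log2 difference of 1.61) ended without T3 replicate 1, at 1.45. The lower call, for dpn (-1.09), ended without T2 replicate 1 or T3 replicate 2 or 3, with values from -1.11 to -1.01. The call for E(spl)mdelta-HLH (a fitted difference of 1.90) ended without T2 replicate 3 or 4 or any 1 T3 array, with values from 1.65 to 1.97. With a pseudocount at the median signal the calls for ac, E(spl)mdelta-HLH and dpn ended (0.80, 0.94 and -0.99). Of 9 segment polarity genes 1, en, was higher, 1 when adjusted over the list alone (camera adjusted p = 0.0023, and adjusted p = 0.098 with an estimated correlation). It had 279 ± 41.1 at T3 and a log2 fold change of 1.86, and its call ended without T2 replicate 1 or 3 or T3 replicate 1 or 3, where the value lay between 1.61 and 1.90. Of 7 pair-rule genes 2, eve and prd, were lower, 2 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.098 with an estimated correlation). The eve call (818 ± 93.9 to 333 ± 55.8) ended without T2 replicate 3 or 4 or T3 replicate 2 or 3, with log2 fold changes from -1.33 to -1.15. The prd call (389 ± 39.0 to 179 ± 50.1) ended without T2 replicate 1, 3 or 4 or T3 replicate 1 or 2, with values from -1.20 to -0.96. With the replicate number as a block the calls for eve, prd, ac and dpn ended (adjusted p in limma 0.076, 0.059, 0.052 and 0.057). Centred on the hybridisation controls the calls for prd, ac, dpn, E(spl)mdelta-HLH, esg and en ended (adjusted p in limma from 0.061 to 0.10), and prd also ended under the other scalings (from 0.051 to 0.098). The initiator caspase gene Dronc (188 ± 42.4 to 53.2 ± 4.89) was the 1 cell death gene of 4 called lower, 1 when adjusted over the list alone (camera adjusted p = 0.58). The median of the list was 0.15 (-0.05 centred on the hybridisation controls) and the mean -0.18 on the log2 scale. Of the 39 proteasome subunits 1, Prosalpha4 (1253 ± 255 to 513 ± 81.9), was called lower, 1 when adjusted over the list alone (camera adjusted p = 0.063). The 12 core subunits had a median of -0.43 (-0.63 centred on the hybridisation controls), with all 12 below 0 as deposited and under the 4 scalings. The 14 regulatory subunits had a median of 0.17 (-0.02 with the same centring), and the difference between the particles was not tested. The other 17 lists did not pass the test.

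In all, 93 probe sets were higher and 108 lower at T3 than at T2, from 77 and 96 genes. The share called higher was 46.3% as deposited, 59.3% (112 and 77) centred on ribosomal proteins and 20.7% (17 and 65) centred on the hybridisation controls. Without T3 replicate 1 there were 56 higher and 71 lower, and without T3 replicate 2 there were 47 and 72. With the replicate number as a block there were 47 and 65, and a fit of the 6 arrays alone called 6 and 9. That fit ended the calls for Msh6, bbg, CadN, Elba3, slam, esg, ac, dpn, E(spl)mdelta-HLH, en, eve, prd, Dronc and Prosalpha4 (adjusted p in limma from 0.063 to 0.16). A pseudocount of 1 ended those for CadN, eve, ac, prd, en and E(spl)mdelta-HLH (from 0.051 to 0.12), and array weights that for prd (0.077).

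The comparison of T4 with T3 covered germ band elongation itself. The Snail family gene wor, active in neuroblasts, rose from 11.3 ± 6.02 to 178 ± 8.94, at least 8.08-fold, and the Notch target E(spl)mdelta-HLH from 37.2 ± 4.21 to 296 ± 44.5. The membrane transporter genes Slc45-1 (16.8 ± 23.5 to 185 ± 61.7) and Smvt (57.2 ± 7.93 to 344 ± 28.7) and Pvr, a receptor tyrosine kinase of hemocytes (3.60 ± 0.656 to 40.2 ± 12.1), also rose. The T3 signal of Pvr lay below the negative-control level, so that its rise is at least 1.78-fold, a bound under 2-fold. Among the strongest falls, SNCF went from 706 ± 117 to 69.7 ± 22.3 and term from 2113 ± 23.7 to 244 ± 35.4. The repressor gene Blimp-1 (160 ± 22.2 to 22.5 ± 18.2) and Pax, which encodes paxillin (340 ± 61.3 to 73.6 ± 16.1), also fell. So did the homeobox gene zen2 (92.4 ± 34.7 to 15.7 ± 8.22), a call that ended without T3 replicate 2 or 3 or T4 replicate 2 or 3 (log2 fold changes from -2.24 to -1.78, adjusted p in limma from 0.061 to 0.11). The pole cell gene pgc went from 65.2 ± 10.7 to 13.7 ± 2.25, at least 2.94-fold lower.

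Of 21 proneural and Notch pathway genes 4 were higher, 5 when adjusted over the list alone (camera adjusted p = 7.9e-05). Of these the calls for l(1)sc (1.16 on the log2 scale) and E(spl)m7-HLH (1.08) each ended without T3 replicate 1 or 3 or T4 replicate 2. So did the former without T4 replicate 3, with values from 1.05 to 1.13, and the latter without T4 replicate 1, with values from 1.01 to 1.10. Of 7 pair-rule genes 1, ftz, was lower (702 ± 27.2 to 174 ± 19.9), 4 when adjusted over the list alone (camera adjusted p = 5.7e-05). Of the 7 zygotic cellularisation genes 2, Z600 and Sry-alpha, were lower, 2 when adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.07 with an estimated correlation), with 59.0 ± 23.6 and 174 ± 34.4 at T4. The median of that list was -0.07 on the log2 scale and 0.04 with arrays centred on the hybridisation controls. Without T3 replicate 2 the call for Z600 ended, at a log2 fold change of -1.25. Of 6 hemocyte, tracheal and salivary gland genes 1 was higher, 2 when adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.07 with an estimated correlation). Of 39 proteasome subunits 1, Prosalpha4, was lower, a call that ended without T3 replicate 1 or 3 or T4 replicate 2 or 3 (adjusted p in limma from 0.053 to 0.079). It was 1 when adjusted over the list alone (camera adjusted p = 0.042 downward, adjusted p = 0.46 with an estimated correlation, 0.29 after quantile normalization and 0.074 with the replicate number as a block). The list had a median of 0.03 and a mean of -0.09 on the log2 scale, the median being -0.05 after quantile normalization and -0.11 centred on the median. The core and regulatory subunits had medians of -0.82 and 0.24, with all 12 core values below 0 as deposited and under the 4 scalings, and their difference was not tested. Centred on the hybridisation controls the calls for Z600, Sry-alpha, l(1)sc, E(spl)m7-HLH, Prosalpha4 and zen2 ended (adjusted p in limma from 0.055 to 0.26). The other 18 lists did not pass the test.

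In all, 72 probe sets were higher and 78 lower at T4 than at T3, from 63 and 73 genes. The share called higher was 48% as deposited, 36.2% (55 and 97) after quantile normalization, 28.1% (47 and 120) with arrays centred on the median and 67.4% (29 and 14) centred on the hybridisation controls. There were 50 higher and 43 lower without T3 replicate 2 and 40 and 50 without T3 replicate 3, and a fit of the 6 arrays alone called 6 and 3. That fit ended the calls for Slc45-1, Pvr, Blimp-1, zen2, Pax, pgc, E(spl)m7-HLH, l(1)sc, Z600, Sry-alpha and Prosalpha4 (adjusted p in limma from 0.052 to 0.20). A pseudocount of 1 ended those for E(spl)mdelta-HLH (0.14), zen2 (0.079), Slc45-1 (0.057), l(1)sc (0.057) and E(spl)m7-HLH (0.051), and E(spl)m7-HLH also fell short with arrays centred on the median, at a log2 fold change of 0.94.

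The comparison of T4 with T0 set the end of the series against its start. The proneural and Notch pathway genes had the largest rise of the lists, with all 21 higher, 21 when adjusted over the list alone (camera adjusted p = 8.6e-19). Tom rose from 24.0 ± 29.5 to 5025 ± 669, a log2 fold change of 7.73 ± 0.44 (SE), and its relative Ocho at least 64.9-fold to 1434 ± 212. The genes bnb and link rose at least 139-fold and at least 119-fold, and Ama, a cell adhesion protein, at least 92.3-fold to 2029 ± 133. Of the 16 maternal egg activation and localised transcripts 15 were lower, 15 when adjusted over the list alone (camera adjusted p = 3.7e-15). The maternal thioredoxin gene dhd went from 6871 ± 815 to 24.1 ± 14.5, exu fell at least 138-fold to 9.10 ± 4.03, and Hsp26 went from 6763 ± 1680 to 49.2 ± 25.5. BicC fell at least 61.0-fold to 4.37 ± 0.321, and swa, which also acts on bicoid RNA, fell at least 47.6-fold to 4.20 ± 2.46. Of 8 glycolysis genes 7 were lower, 7 when adjusted over the list alone (camera adjusted p = 4.9e-09), with Gapdh1 at 93.3 ± 34.9 and Pglym78 going from 2185 ± 392 to 79.3 ± 48.4.

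The gap, pair-rule, segment polarity, dorsal ectoderm, mesoderm, neurogenic ectoderm, Hox, hemocyte and zygotic cellularisation lists were higher, with camera adjusted p between 4.6e-08 and 0.012. Of their members 10 of 12, 7 of 7, 7 of 9, 11 of 13, 6 of 9, 3 of 3, 3 of 4, 4 of 6 and 4 of 7 were called higher. The counts adjusted over the list alone were 10, 7, 7, 11, 6, 3, 4, 4 and 4. The cellularisation list also held 1 lower gene, slam (486 ± 49.5 to 109 ± 9.86). Of 9 pole cell and germ plasm genes 7 were lower, 7 when adjusted over the list alone (camera adjusted p = 1.8e-08). The calls of 5 further lists were lost with an estimated correlation. Of the 7 genes of the sex chromosome counting list 4 were higher, 4 when adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.095 with an estimated correlation). Of 19 polarity machinery genes 8 were higher and 1 lower, 8 and 1 when adjusted over the list alone (camera adjusted p = 0.0067, and adjusted p = 0.15 with an estimated correlation). Of 5 heat shock genes 2 were lower, 2 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.026, and adjusted p = 0.064 with an estimated correlation). None of the 36 cytoplasmic ribosomal proteins was called in limma, although 29 had an unadjusted p under 0.05. Their median was 0.74, with 0 called when adjusted over the list alone (camera adjusted p = 1.3e-06, adjusted p = 0.15 with an estimated correlation and 0.13 after quantile normalization). Centred on ribosomal proteins the median was 0.04, near 0 by construction because this same list was used for the centring. Of 39 proteasome subunits 6 were lower and 1 higher, 6 and 1 when adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.18 with an estimated correlation). The cell cycle, late differentiation, eggshell, cell death and mitochondrial ribosomal lists did not pass the test. Among the cell death genes Dark, an activator of caspases, rose from 34.5 ± 8.32 to 139 ± 8.94 and Dronc fell from 199 ± 11.7 to 25.6 ± 13.1.

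In all, 1664 probe sets were higher and 1716 lower at T4 than at T0, from 1336 and 1488 genes. The median log2 fold change of all probe sets was 0.19, over 0.1, and changes as deposited were not centred on it. The share called higher was 49.2% as deposited, 36.2% (1200 and 2118) with arrays centred on the median, 16.6% (681 and 3424) centred on ribosomal proteins and 26.7% (899 and 2469) centred on the hybridisation controls. Of the 1716 lower probe sets 1099 (64.0%) were called lower from T0 to T1 and 343 (20.0%) from T1 to T2, and 285 (16.6%) in none of the 4 steps. Of the 1664 higher ones 630 (37.9%) were called higher from T0 to T1 and 806 (48.4%) in none of the steps. Simulated data without any change shared 0 and 0 calls of T1 and T4 against T0, an outcome all but fixed in advance that cannot show what shared arrays add. Independent lists would share 258 of the lower and 130 of the higher calls. Part of the excess may come from the shared T0 arrays, which cannot be split into parts that each keep several.

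Transcripts higher on average during cellularisation than before and after it formed a class. Their mean of T1 and T2 exceeded T0, and also the mean of T3 and T4, by at least 1 on the log2 scale. The adjusted p in limma was under 0.05 in each test. Being an average, this rule does not require a higher signal at T2. There Elba2, chosen after its values were seen, had 842 ± 88.6 against 888 ± 235 at T0. This class held 83 probe sets, from 78 genes. The mean was higher at T1 than at T2 in 68 of the 83, and 81 were called higher from T0 to T1. The mean lay below the negative-control level in 47 at T0 and in 20 at T4. By the smaller of both fitted differences the leading members were Z600, Elba3, CG14915, CG15876, CG13713, bard, CG13000, SNCF and Sry-alpha, beside 1 probe set with no single gene symbol. All but Sry-alpha had a T0 mean below the negative-control level, as had Elba3, CG15876, CG13713 and CG13000 at T4, so that their fitted differences are not exact and set no order among them. Other members kept a signal outside cellularisation, such as Elba2 at T0 (888 ± 235) and halo at T4 (421 ± 58.5), chosen after their values were seen. CG14915 had 4129 ± 74.4 at T1, 2683 ± 194 at T2 and 57.6 ± 15.9 at T4. Of the 7 measured zygotic cellularisation genes 6 were in the class. The exception was kuk, which exceeded T0 by 2.09 ± 0.14 (SE) but the later stages by 0.32 ± 0.12 (SE), with 2865 ± 242 at T4. Over the 5 stages 6161 of the 13966 probe sets changed in the moderated F test. The class held 137 probe sets with arrays centred on the median and 47 with arrays centred on ribosomal proteins.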

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

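The test of array scaling for the ribosomal protein transcripts was chosen only after the result was seen, and the other tests had been set out earlier. A signal stood out in probe sets that no comparison used. The 3 control probe sets for GAPDH had a mean signal of 4003 ± 481 at T0, 35.1 ± 10.6 at T1, 64.2 ± 51.9 at T2, 30.8 ± 6.00 at T3 and 18.6 ± 7.80 at T4 (n = 3 arrays each). All 3 probe sets lay above the negative-control level of 21.96 at T0 and T2, whereas 1 lay below it at T1 and 2 at T3 and T4. Among the tested probe sets, Gapdh1 went from 2707 ± 185 at T0 to 332 ± 59.8 at T1.

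The 36 measured cytoplasmic ribosomal protein transcripts stood 0.62 higher at T1 than at T0 on the log2 scale, and none was called. The 9 hybridisation-control probe sets, whose RNA does not come from the embryos, themselves stood 0.51 higher in the median. With arrays centred on these controls 19.7% of the ribosomal shift was left, a median of 0.12, so array scaling may account for most of it. Whether the amount of control RNA was equal on all arrays was not tested, so a biological rise of these transcripts stays open.

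Other splits of the arrays were counted for each comparison. For each pair of stages 1 of 10 splits, the real one, called as many probe sets, and 10 splits are too few for a share under 0.05. The real and highest other counts were 3189 and 0 for T1 against T0, 1347 and 2 for T2 against T1, 201 and 5 for T3 against T2, 150 and 1 for T4 against T3, and 3380 and 0 for T4 against T0. For changes at any stage 1 of 100 assignments of the 15 arrays to the stages, the real one, gave as many (6161 against 400 for the highest other). A random grouping of these arrays thus rarely gives as many. If the replicates of a stage came from the same collection, differences between collections could give this count too, so that source is not excluded. For the cellularisation class 2 of 100 gave as many, 83 in the real one and 157 in the highest other. The share was below the limit set beforehand, but a wrong grouping gave a larger class. Shuffled arrays keep the differences between the real stages, which can also form a class. This count therefore cannot decide, and chance is not excluded.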

How the results depend on the processing

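Centring on hybridisation controls was chosen after seeing the data, and the other tests were planned, except for the transcripts low at T1. Probe sets called higher and lower changed by over 1.5 times as follows, and the cause was not tested unless given. Centred on the median, T1 against T0 had 1716 higher, T2 against T1 421 higher, T4 against T3 47 higher and 120 lower, the class 137 and the low-at-T1 group 546. Centred on ribosomal proteins, T1 against T0 had 299 higher and 3626 lower, T4 against T0 681 and 3424, and the class 47. Centred on hybridisation controls, T1 against T0 had 342 higher, T2 against T1 376 lower, T3 against T2 17 higher and 65 lower, T4 against T3 29 and 14, and T4 against T0 899 higher. With a pseudocount of 1, T3 against T2 had 55 higher and 68 lower and T4 against T3 43 higher. With a pseudocount at the median signal, T1 against T0 had 680 higher, T2 against T1 346 higher, T3 against T2 69 lower, T4 against T0 1048 higher and the low-at-T1 group 483. With only the 2 stages compared, which leaves fewer arrays to estimate the spread, T3 against T2 had 6 higher and 9 lower and T4 against T3 6 and 3. With the replicate block T3 against T2 had 47 higher and 65 lower, and it changed no other count by over 1.5 times. Whether arrays with the same number share a batch stays open. After removal of the stage means the 23 pairs of arrays with the same number correlated between -0.042 and 0.075, with 0 over 0.1. Yet 8 of 15 arrays correlated best with an array of their own number, and the count given by chance was not computed. With single arrays left out, T3 against T2 had 47 to 102 higher and 71 to 124 lower and T4 against T3 40 to 89 and 43 to 80, while the other counts stayed within 1.5 times. Of 47 list shifts 31 were called with an estimated correlation. After quantile normalization 49 list shifts were called, with 3 of the 47 lost, namely cytoplasmic ribosomal proteins for T1 against T0 (adjusted p in camera 0.21) and T4 against T0 (0.13) and proteasome subunits for T4 against T3 (0.29). Centred on the median 50 were called, with 0 of the 47 lost. With the replicate block 45 were called, with 2 lost, heat shock genes for T1 against T0 (0.057) and proteasome subunits for T4 against T3 (0.074). No call turned to the opposite direction. Of 132 named gene and comparison pairs 124 were called and 92 kept the call under every alternative and left-out array. Between 39.0% and 49.7% of the signals of an array lay below background, which limits folds of dim genes.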

Other observations

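The group of transcripts low at T1 was noticed in the data, and its tests were run on the same data, while the tests below had been set out before their results were seen. Of the 2097 probe sets called lower from T0 to T1, 835 (39.8%) had a mean of T3 and T4 at least 1 higher on the log2 scale than T1, with an adjusted p under 0.05 in limma. This overlap was 0 in simulated data without any change, an outcome all but fixed in advance that cannot show what shared arrays add. Independent lists would share 231, and part of the excess may come from the shared T1 arrays. The T1 mean lay below the negative-control level of 21.96 for 326 of them, and with a pseudocount at the median signal 57.8% stayed in the group. The rule for the group did not use T2. From T1 to T2 372 of the 835 were called higher, so for the others a low confined to T1 is not shown. At T4 191 of the 835 were called lower than at T0, 625 were not called and 19 were called higher. Genes of DNA replication were among them. Prim2 was noticed first, and RPA1 and Mcm3 came from a list of replication genes written before their values were seen, and were picked from it as examples afterwards. Prim2 went from 436 ± 63.4 at T0 to 7.10 ± 0.600 at T1 and 423 ± 123 at T4 (n = 3 arrays each), RPA1, a single-strand DNA binding protein, from 818 ± 125 to 41.3 ± 9.20 and 657 ± 71.5, and Mcm3, a helicase subunit, from 375 ± 28.8 to 85.5 ± 17.6 and 562 ± 42.5. Against 39.8% of all lower probe sets, the group held 0 of the 12 lower maternal egg activation transcripts, 0 of 3 lower heat shock genes, 1 of 6 lower glycolysis genes, 2 of 7 lower pole cell genes, 3 of 6 lower cell cycle genes, 9 of 14 lower mitochondrial ribosomal proteins and 5 of 6 lower proteasome subunits, and differences between these lists were not tested.

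Technical sources of this group were weighed against a biological one. Over 4 scalings at least 65.4% of its probe sets stayed in it, and with 1 T1 array left out at least 86.6%, which argues against the scaling of the T1 arrays and against 1 deviating T1 array as the whole source. In 1 of 100 assignments of the arrays to the stages, the real one, the group was as large (835 against 14 for the highest other). Because the group was defined after it was seen in these same arrays, this count cannot exclude chance. Of 30 measured replication genes not seen before, 18 were called lower from T0 to T1 and 17 of these (94.4%) were in the group, against 713 of 1763 other genes (40.4%; Fisher's exact test, one-sided, p = 2.6e-06). The test counts genes as independent, although they share the same arrays and may vary together. Its p therefore does not measure the spread between embryos or arrays. A loss of maternal RNA followed by zygotic transcription may give the course of this group, as a hypothesis that was not tested.

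Genes of the cellularisation class were next to each other in the genome more often than in random lists. Among 78 class genes there were 4 pairs of neighbouring genes, insv with Elba2, CG15876 with CG13713, CG13713 with CG13712 and CG14427 with nullo, chosen after their values were seen. Random lists of measured genes had a mean of 0.45 pairs, a 95th percentile of 2 and a highest count of 4 (10000 lists, permutation p = 0.0015, one-sided). Cross-hybridising probe sets could give such pairs. Within stages 0 of the pairs correlated above 0.9 (r from -0.29 to 0.21). Probe sets known to share a transcript were not compared in this way, so cross-hybridisation is not excluded. Shared regulation of neighbouring genes may explain the pairs, as a hypothesis that was not tested.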
